A study of Mus musculus with 6 samples.

How the data were processed

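RNA from 4T1-LM3 mouse mammary carcinoma cells was sequenced in 6 samples, 3 with control CM and 3 with CM from Tdo2high MFs. Per the labels' protocols, polyA RNA was copied into cDNA with random hexamers and the libraries were built and sequenced at BGI. Per the submitters' processing notes the build was GRCm38; the aligner, the quantifier and the annotation are not given in the sources used here. The authors deposited 1 table of FPKM (fragments scaled by transcript length and by the library's mapped fragments), per the file headers, for 16426 genes named by NCBI gene number and symbol, rounded to 2 decimals. FPKM already corrects for library size and transcript length, so a change in a few abundant genes shifts all other values, and low values carry rounding error. A total of 29 genes are listed at 0 in all libraries and no mitochondrially encoded mRNA was analysed here. Samples were assigned to groups by their titles, which match the column names.

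Low values were examined for steps of whole reads. Among 3739 values of up to 0.6 FPKM, the mean distance to a whole multiple of the gene's smallest value was 0.259, against 0.257 after values were exchanged between genes (100 exchanges). Whole reads were not recovered this way, but rounding to 2 decimals can blur steps of whole reads at such low values. The depth of each library is therefore not known here, no counting interval is given and no count model was used. The number of libraries and the spread between them set the precision.

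Genes were kept with at least 1 FPKM in at least 3 of the 6 libraries (10804 genes, 5622 left out). Values were tested as log2(FPKM + 1), with no further scaling, by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, no replicate block), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. With 3 samples against 3, an exact two-sided permutation test of a single value cannot go below 0.1, so none is reported. Intervals are 95% intervals of the moderated fit. The 28 gene lists were written before the data were examined, as were the groups, the tests and all but 1 of the alternative settings. Lists with at least 5 tested members (22) were tested by camera with its preset correlation of 0.01, adjusted over those lists, and again with an estimated correlation and with fry. A total of 10 lists passed with the preset correlation, 3 with an estimated correlation (NRF2 targets, ferroptosis suppressors and the ATF4 amino acid response) and 10 by fry, which asks whether a list's genes move one way on balance; 20 passed fry's test of change in either direction. The estimated correlation was -0.024 for cholesterol synthesis, -0.003 for mesenchymal genes and 0.002 for MHC class I presentation and PD-L1, below the preset 0.01. A higher correlation was thus not what ended the calls of those lists. Ferroptosis suppressors, at an estimated correlation of -0.002, also went from adjusted p = 3.92e-06 to 0.0448 by camera. The run with an estimated correlation was therefore stricter even at a correlation below the preset. A call lost in it is no sign by itself that the genes move together. Counts adjusted over the list alone use the members of that list as the only family. The list of mitochondrially encoded mRNAs had 0 members in the table.

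Genes were named by a rule written in advance: the 8 largest rises and 8 largest falls with adjusted p under the threshold and no overlap of the groups, leaving out predicted genes and pseudogenes; a fixed set of AhR and ferroptosis genes whether or not they passed; up to 4 called members per list with the largest change; and the 5 most abundant called genes with at least a 1.5-fold change. Some genes that the rule chose are not written out in the report. Other list members, named as examples or as members that did not pass, were chosen after their values were seen. Gene positions come from the RefSeq annotation of the same build, which held 16371 of the gene numbers. A total of 26 symbols had turned into dates and were replaced through the gene number.

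The test was tried on simulated data drawn from the mean and spread of the 10804 genes, with 200 genes changed in each of 5 draws. It recovered 53.2% of genes changed 1.2-fold, 89.3% at 1.5-fold and 96.8% at 2-fold, and 5.16% of the calls were false. Genes were drawn independently of each other, so these rates need not hold for the real libraries. The alternatives were other pseudocounts, filters, scalings and variance models, a replicate block, a fold minimum, and leaving out each library in turn. A correction of each library for GC content and transcript length (10537 genes with both) was added after seeing the data. Figures were drawn with matplotlib 3.10.9.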

Results

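Messenger RNA was profiled in 4T1-LM3 cells, a mouse mammary carcinoma line, after culture in conditioned medium (CM), which carries what the donor cells released. In 3 samples the medium came from matrix fibroblasts (MFs) described as Tdo2high, and 3 samples received a control medium whose cell source the labels do not give. Tdo2 encodes tryptophan 2,3-dioxygenase, which opens the route from tryptophan to kynurenine. Each library is given as FPKM for 16426 genes, of which 10804 passed the expression filter and were tested. FPKM summed to between 438603 and 447415 per library, and 10765 to 10791 genes reached 1 FPKM. Read depth is unknown, since the values are rounded FPKM. Pearson's r of log2(FPKM + 1) across genes was 0.997 to 0.998 between libraries of one group and 0.996 between libraries of different groups. The first principal component held 42.7% of the variance and separated the groups. The labels do not say that the samples of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

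The comparison asked how medium from Tdo2high fibroblasts changed gene expression in the carcinoma cells, relative to the control medium. No samples were labelled as given medium from fibroblasts low in Tdo2, or kynurenine alone. Effects of Tdo2 thus cannot be told apart from those of other differences between the media. After Tdo2high CM, 17 of 21 tested NRF2 targets rose and none fell. Nqo1, a quinone reductase, rose 2.87-fold, from 13 ± 0.505 to 37.3 ± 0.501 FPKM (SD, n = 3 per group). Aldh3a1, an aldehyde dehydrogenase outside the list fixed for NRF2 targets, rose 2.84-fold, from 12.2 ± 0.754 to 34.7 ± 0.461 FPKM. Of 28 tested genes of the ATF4 amino acid response, 13 fell and 1 rose. The largest of these falls was that of Ddit3, a stress transcription factor, which went from 11.1 ± 0.229 to 6.72 ± 1.13 FPKM. In all, 801 genes (7.41% of those tested) changed at an adjusted p under 0.05 by limma, 362 higher and 439 lower. Scaling by the median of ratios gave 455 higher and 367 lower.

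Most changes were small. The median fold of the changed genes was 1.16, and 29 higher and 8 lower genes passed 1.5-fold. Among the 8 largest named rises, Osgin1, an oxidative stress response gene, had a log2 fold change of 1.23 ± 0.06 (SE), Neurl3 of 1.21 ± 0.05, the glutathione transferase Gstm1 of 1.05 ± 0.03, S100a8 of 1.03 ± 0.09 and F13a1, the A chain of coagulation factor XIII, of 0.89 ± 0.04. These folds are on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes. Among the largest named falls were Angptl6 (-0.74 ± 0.09), Cd74, the invariant chain (-0.69 ± 0.10), Chchd10, a mitochondrial protein gene (-0.65 ± 0.07), Atf5, a stress-induced transcription factor (-0.60 ± 0.05), and Ly6a (-0.53 ± 0.05). Cd300ld3 had -0.80 ± 0.15, a call that ended with no filter on low values (adjusted p = 0.0711 by limma). Zfp965 (-1.58 ± 0.32) and Zfp973 (1.39 ± 0.32) are members of a cluster of related genes on chromosome 2 that can share reads, so their values are uncertain. Over the alternative settings their log2 fold changes ran from -3.00 to -1.24 and from 1.16 to 3.38. Their calls ended in 6 and 8 of 16 alternatives, among them robust variance estimates, at adjusted p = 0.126 and 0.145 by limma. In the 801 changed genes the groups did not overlap in any case, which follows largely from how they were chosen and is no separate evidence. Among all tested genes 29.2% showed no overlap, where chance gives 10% on average. Any other difference between the 2 sets of samples would also raise that share. Leaving out any 1 library reduced the count to between 395 and 559 genes.

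**Figure D1:**
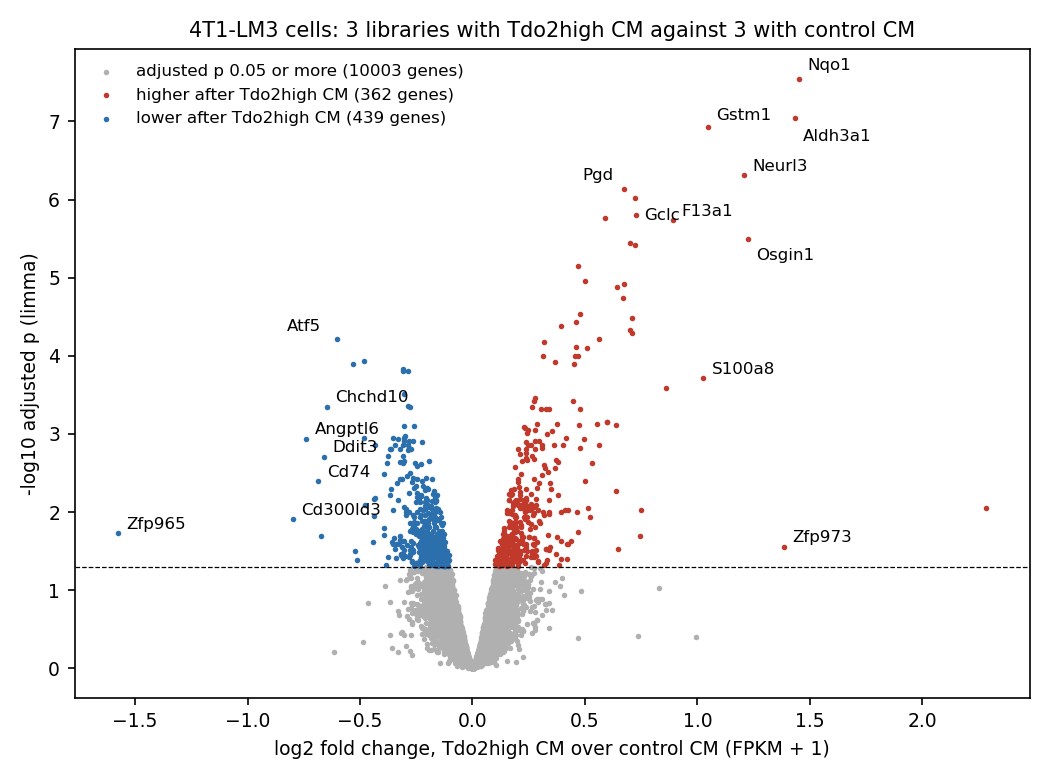
Each point is 1 of the 10804 tested genes, with its log2 fold change (Tdo2high CM over control CM, FPKM + 1) on the x axis and -log10 of its limma adjusted p on the y axis; the dashed line marks 0.05. The 362 red genes were higher and the 439 blue genes lower, with Nqo1 and Aldh3a1 at the upper right, and the unlabelled point farthest right is a predicted gene.

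NRF2 is a transcription factor that switches on antioxidant and detoxifying genes. Of 21 tested members of the list fixed for its targets, 17 rose and none fell by limma, and the same 17 and 0 held when adjusted over the list alone. The median log2 fold change was 0.37, and camera called the list higher (adjusted p = 2.06e-26), a call that held at adjusted p = 0.0448 with an estimated correlation. Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis, went from 13.9 ± 0.0985 to 23.6 ± 0.395 FPKM, and its partner Gclm from 14.1 ± 0.829 to 17.4 ± 0.662. Pgd, an enzyme of the pentose phosphate pathway, rose from 116 ± 1.49 to 186 ± 4.30 FPKM and malic enzyme Me1 from 29.5 ± 1.10 to 37.6 ± 0.815. The thioredoxin reductase Txnrd1 rose from 64.2 ± 1.35 to 97.0 ± 1.18 FPKM. Mgst1, a microsomal glutathione transferase outside the list, rose from 88.9 ± 3.07 to 145 ± 5.77 FPKM. The 4 members that did not pass were Hmox1 (log2 fold change 0.24, and 0.15 to 0.39 without 1 library; adjusted p = 0.272), Sqstm1 (0.06), Ugdh (0.05) and Taldo1 (-0.05). Gstm1 has close paralogs, so part of its value can come from shared reads. On GRCm38, Nqo1 lies on chromosome 8 from 107388225 to 107403205, Gclc on chromosome 9 from 77754535 to 77794489 and Pgd on chromosome 4 from 149149991 to 149166705.

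The study's title names ferroptosis, a form of cell death driven by iron-dependent lipid peroxidation. Of 17 tested ferroptosis suppressors, 7 rose and none fell, with 8 higher and 0 lower when adjusted over the list alone; camera called the list higher (adjusted p = 3.92e-06, and adjusted p = 0.0448 with an estimated correlation). Slc7a11, the cystine importer that feeds glutathione synthesis, rose 1.69-fold, from 2.21 ± 0.172 to 3.73 ± 0.238 FPKM. The ferritin chains Fth1, from 1952 ± 136 to 2601 ± 10.9 FPKM, and Ftl1, from 2010 ± 153 to 2788 ± 28.8 FPKM, rose as well; both have processed copies in the genome that can share reads. Of the 7 risers, 6 also stand on the NRF2 list, and the other was Scd1, a fatty acid desaturase (0.11). The call of Scd1 ended in 9 of 17 alternatives, among them the TPM scale (adjusted p = 0.0651 by limma) and every fit without 1 library. The 11 tested suppressors outside the NRF2 list had a median log2 fold change of -0.0012. Gpx4, the peroxidase that removes lipid peroxides, had 353 ± 15.2 FPKM with control CM and 377 ± 0.556 with Tdo2high CM (0.10, 95% interval 0.02 to 0.17, adjusted p = 0.114). Gpx4 passed the test without control CM replicate 2 (adjusted p = 0.0219 by limma) and with a GC and length correction added after seeing the data (0.0257). Slc3a2, the heavy chain that pairs with Slc7a11, had a log2 fold change of -0.02 (95% interval -0.09 to 0.06). Slc7a11 lies on chromosome 3 from 50364936 to 50499087, and Gpx4 on chromosome 10 from 80047166 to 80056439.

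Ferroptosis promoters and markers gave no such shift. Of 17 tested, 1 fell and none rose, and the count adjusted over the list alone was the same; at adjusted p = 0.894 camera did not call the list. The list's median was 0.0092 and its mean -0.015, and camera placed it higher. The member that fell was Trp53, from 26.0 ± 0.439 to 20.6 ± 1.28 FPKM. Acsl4, which loads polyunsaturated fatty acids into lipids, had a log2 fold change of 0.03 (95% interval -0.03 to 0.09). Those of the transferrin receptor Tfrc (0.11), Ptgs2 (0.09) and Chac1 (-0.16) did not pass either, at adjusted p = 0.134, 0.227 and 0.128 by limma.

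**Figure D2:**
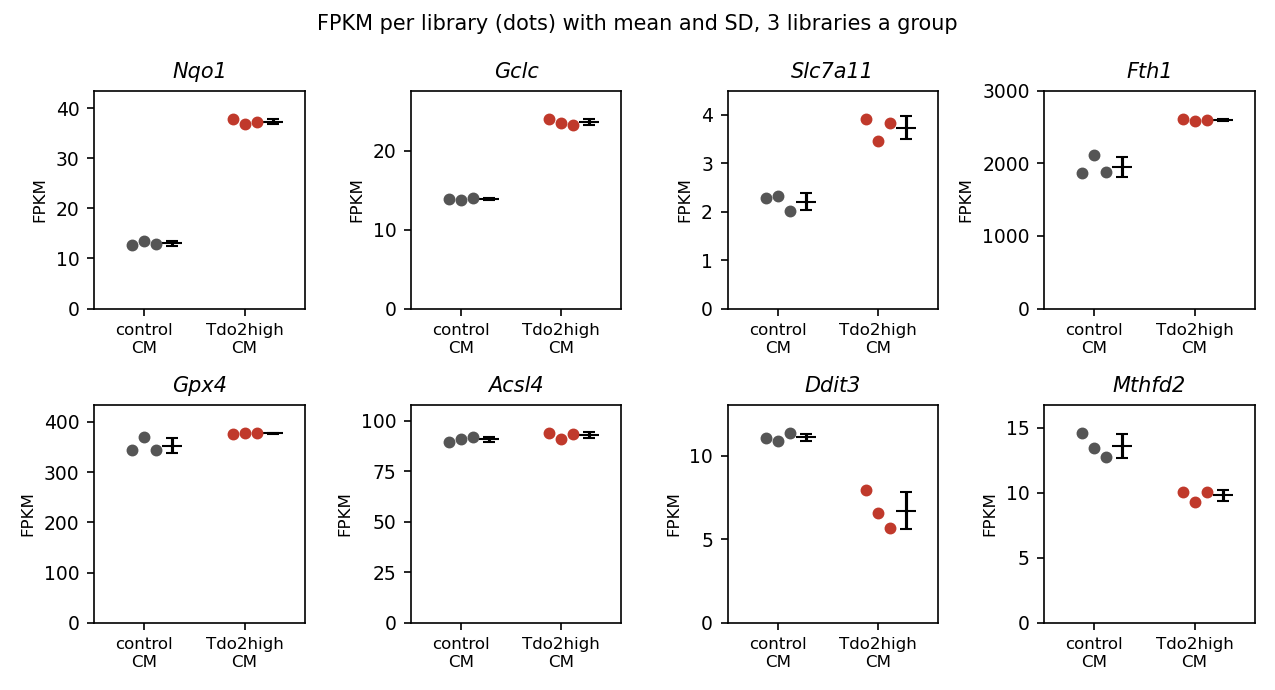
FPKM of 8 genes in each library (dots), with the mean and SD of 3 libraries per group beside them and y axes from 0. The libraries of the 2 groups lie apart for Nqo1, Gclc, Slc7a11, Fth1, Ddit3 and Mthfd2. They also lie apart for Gpx4, where the ratio of group means is 1.07, and overlap for Acsl4, where it is 1.02.

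Kynurenine is a ligand of the aryl hydrocarbon receptor (AhR). Of 8 tested members of the list of AhR and its targets, 5 rose and none fell; adjusted over the list alone, 6 were higher and 1 lower. Camera called the list higher (adjusted p = 2.70e-06), but not when the correlation was estimated from the data (adjusted p = 0.0897 with an estimated correlation). The largest rises were those of Nqo1 and Aldh3a1. Cyp1b1, a cytochrome P450, went from 81.4 ± 0.775 to 91.2 ± 1.10 FPKM, and Tiparp, a feedback inhibitor of the receptor, from 19.8 ± 0.892 to 23.8 ± 1.01 FPKM. Ugt1a6a, a glucuronosyltransferase that shares exons with its neighbours, rose from 0.453 ± 0.211 to 1.29 ± 0.454 FPKM. Its call ended in 7 of 16 alternatives, among them no filter on low values (adjusted p = 0.101 by limma). Ahr itself had 9.24 ± 0.195 and 10.1 ± 0.312 FPKM (adjusted p = 0.163). Of the 14 members fixed for this list 10 were in the table, and Cyp1a1 was not among them. Tdo2 stood at 0.167 ± 0.0351 FPKM with control CM and 0.147 ± 0.0681 with Tdo2high CM, below the filter. Of the 13 tryptophan and kynurenine genes in the table, Tdo2 included, 4 passed the filter, and none of the 4 changed, also when adjusted over the list alone.

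ATF4 drives genes for amino acid synthesis, transfer RNA charging and stress signalling. Of 28 tested members of its list, 13 fell and 1 rose, and adjusted over the list alone 20 were lower and 1 higher. The median log2 fold change was -0.18, and camera called the list lower (adjusted p = 3.59e-07, and adjusted p = 0.0448 with an estimated correlation). Besides Ddit3, the falls were led by Mthfd2, a mitochondrial folate enzyme, from 13.6 ± 0.926 to 9.81 ± 0.425 FPKM, and Aars, alanyl-tRNA synthetase, from 48.7 ± 0.958 to 38.2 ± 2.40 FPKM. The serine synthesis genes Phgdh (-0.29) and Psat1 (-0.21) and asparagine synthetase Asns (-0.30) fell too. Slc7a11, which is also an NRF2 target, was the member that rose. Atf4 mRNA had a log2 fold change of -0.08 and did not pass. The lists of the unfolded protein response and of heat shock were not called by camera, at adjusted p = 0.433 and 0.389. Among unfolded protein response genes Xbp1 rose (0.24) and Hyou1 fell (-0.18), 1 of 15 each way, or 1 higher and 2 lower adjusted over the list alone. Of 10 heat shock genes, 2 fell, Hsp90aa1 (-0.14) and Hspd1 (-0.10), with the same count adjusted over the list alone.

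**Figure D3:**
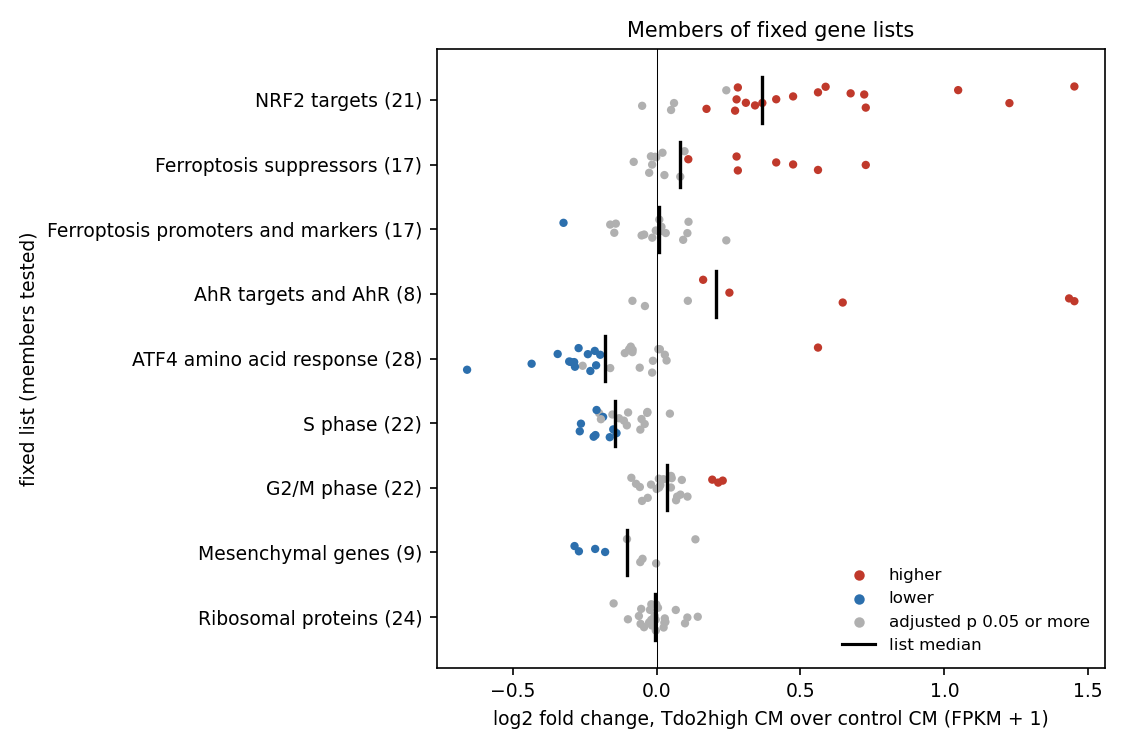
Log2 fold changes (x axis, Tdo2high CM over control CM, FPKM + 1) of the tested members of 9 fixed lists, with the number tested after each name; dots are genes, coloured by the limma call, and black bars are list medians. NRF2 targets lie mostly to the right (median 0.37) and ATF4 and S phase genes mostly to the left (-0.18 and -0.14), while ribosomal protein genes centre on 0.

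Of 22 tested S phase genes, 9 fell and none rose, 16 and 0 adjusted over the list alone. The median was -0.14, and camera called the list lower (adjusted p = 3.59e-07, but adjusted p = 0.103 with an estimated correlation). The replicative helicase subunit Mcm5 (-0.21) and the licensing factors Cdt1 (-0.27) and Cdc6 (-0.26) were among them. Of 22 G2/M genes, 3 rose and none fell, with the same count adjusted over the list alone: Mki67 (0.23), Cenpf (0.21) and Cenpe (0.19). Camera called the list higher at adjusted p = 0.025, a call that ended at adjusted p = 0.240 with an estimated correlation, and also under quantile normalization and without any 1 of 3 libraries (control CM replicate 1, Tdo2high CM replicates 2 and 3).

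Of 9 tested mesenchymal genes, 4 fell and none rose (1 higher and 4 lower adjusted over the list alone): fibronectin Fn1, from 316 ± 14.4 to 259 ± 4.66 FPKM, Snai1 (-0.27), Twist1 (-0.21) and Sparc (-0.18). Camera called the list lower at adjusted p = 0.00958, but adjusted p = 0.116 with an estimated correlation. Of 20 cholesterol synthesis genes, 3 rose and none fell, 5 and 0 adjusted over the list alone: Insig1 (0.27), Stard4 (0.21) and Cyp51 (0.17). Camera called this list higher at adjusted p = 0.00116, but adjusted p = 0.0897 with an estimated correlation. Of 15 fatty acid genes, 3 rose, Me1, Fads2 (0.24) and Scd1, and 4 adjusted over the list alone; camera did not call the list (adjusted p = 0.101), which it placed higher with a median of -0.0012 and a mean of 0.05. That list was called higher by fry (adjusted p = 0.00342) and with the correction for GC content and length (0.0478), added after seeing the data. Among 22 nuclear OXPHOS subunits 1 rose, Cox4i1 (0.19), the same count adjusted over the list alone. Camera called that list higher at adjusted p = 0.00958, but adjusted p = 0.553 with an estimated correlation, and the call also ended by fry, under quantile normalization, without control CM replicate 1 and with the correction for GC content and length (adjusted p = 0.109). None of 24 ribosomal protein genes changed (median -0.0051, mean -0.0019, placed higher by camera), also when adjusted over the list alone, and camera gave adjusted p = 0.737; without control CM replicate 2 it called that list higher, at adjusted p = 0.0251. Of 17 epithelial genes with values, only 3 passed the filter (Krt8, Krt18 and Ocln). None of the 3 changed, also when adjusted over the list alone. Below the filter, Cdh1 did not exceed 0.02 FPKM and Epcam did not exceed 0.11 FPKM. With control CM the mean FPKM was 272 for Krt8, 356 for Krt18 and 1.23 for Ocln. That of the mesenchymal gene Vim was 1274.

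Of 12 tested genes of MHC class I presentation and PD-L1 (Cd274), 2 fell, Tap2 (-0.16) and H2-D1 (-0.12), and 3 adjusted over the list alone. Camera called the list lower (adjusted p = 0.0114, but adjusted p = 0.116 with an estimated correlation). The call of H2-D1 ended in 11 of 17 alternatives, among them the median of ratios (adjusted p = 0.0836 by limma) and every fit without 1 library. Of 27 interferon response genes, 3 rose and 5 fell, 4 and 8 adjusted over the list alone, with Irf7 from 263 ± 3.48 to 212 ± 3.89 FPKM and Cxcl10 from 4.92 ± 0.411 to 6.53 ± 0.743 FPKM; camera gave adjusted p = 0.619. Of 16 NF-kB cytokine genes, Cxcl5 (0.53), Lcn2 (0.42) and Csf3 (0.32) rose and Tnfaip3 (-0.36) and Ccl5 (-0.35) fell, 3 and 3 adjusted over the list alone (camera adjusted p = 0.894). Of 14 immediate early genes, 2 rose and 5 fell, 2 and 7 adjusted over the list alone. Among them were Ier3 (0.42), Ier2 (-0.52), Zfp36 (-0.51) and Jun (-0.37). For this list camera gave adjusted p = 0.0731 (adjusted p = 0.582 with an estimated correlation). The list was called lower under the median of ratios (0.0398), without control CM replicate 1 (0.0481) and without Tdo2high CM replicate 3 (0.00159), and the adjusted p without 1 library ran up to 0.22. The lists of TGF-beta targets (1 of 13 higher, 2 lower; 1 and 3 adjusted over the list alone), p53 targets (1 of 13 higher, 2 lower; 2 and 2 adjusted over the list alone) and hypoxia (1 of 19 higher, 3 lower; 3 and 3 adjusted over the list alone) were not called, at camera adjusted p = 0.815, 0.458 and 0.894. The medians of the NF-kB, TGF-beta and hypoxia lists were below 0 (-0.01, -0.03 and -0.0087) while camera placed them higher; the mean of the NF-kB list was 0.01 and those of the TGF-beta and hypoxia lists were -0.001 and -0.02. The largest changes in the TGF-beta, p53 and hypoxia lists were those of Id2 (0.46), Bbc3 (-0.38) and P4ha2 (-0.27).

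Most markers of other cell types were low, but some were clearly expressed with either medium. With control CM the mean FPKM of fibroblast markers was 41.9 for Pdgfra, 23.6 for Pdgfrb and 15.5 for Dcn. The endothelial markers Eng and Egfl7 had 55.2 and 8.47 FPKM, and the myeloid marker Cd14 had 6.997 FPKM. Of 14 fibroblast markers in the table, 9 stayed below 1 FPKM in every library, and Col1a1, a main collagen of fibroblasts, did not exceed 0.12 FPKM. Of the 5 tested, Npnt, from 31.2 ± 1.04 to 43.2 ± 1.6 FPKM, and Pdgfra (0.17) rose and Dcn (-0.48) fell, 2 and 1 also adjusted over the list alone (camera adjusted p = 0.349). Of 3 tested myeloid markers, S100a8 rose, 1 of 3, or 2 adjusted over the list alone; Lyz2, Csf1r, Itgam and Laptm5 stayed at or under 0.1 FPKM. None of the 7 lymphocyte markers reached the filter, and of 2 tested endothelial markers none changed, also when adjusted over the list alone. Of the 22 lists with at least 5 tested members, 10 were called by camera, 6 higher and 4 lower, and 3 held with an estimated correlation.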

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

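The correction for GC content and length was chosen after seeing the data; all other settings here were fixed before. Of 79 called named genes, 49 kept their direction and call under every alternative run in which they were tested, apart from the fold minimum, which was applied to the gene counts alone, among them Nqo1, Aldh3a1, Gclc, Slc7a11, Fth1 and Ddit3. The other 30 lost the call under at least 1. Those in the report were Zfp973, Zfp965, Cd300ld3, Ugt1a6a, Hsp90aa1, Hspd1, Cxcl10, Tap2, H2-D1, Lcn2, Twist1 and Cdt1. They also included Cdc6, Cenpf, Cenpe, P4ha2, Stard4, Cyp51, Scd1, Ier2, Zfp36, Ier3 and Cox4i1. The NRF2, ferroptosis suppressor and ATF4 lists kept their calls, at adjusted p of at most 0.0448. Against 801 genes (362 higher, 439 lower), no filter on low values gave 394 (199 and 195), where more genes were tested, and eBayes without trend gave 525 (277 lower), for which the cause was not tested. A log2 fold change of at least 1 left 9 genes (8 and 1), a stricter rule by construction. Without 1 library, with fewer samples, the count was 440, 559 and 501 without control CM replicates 1, 2 and 3, and 486, 395 and 440 without Tdo2high CM replicates 1, 2 and 3 (209 to 293 higher, 186 to 266 lower). The number of lists called was 10 and fell to 3 with an estimated correlation, where the AhR list had adjusted p = 0.0897 (8.99e-07 to 0.0897 over its alternatives); leaving out 1 library gave 9 to 11. The lowest r between libraries, 0.9956, was 0.9932 with a pseudocount of 0.1 and 0.9979 with no filter, and mean Tdo2 was 0.353 on the TPM scale, a change of unit.

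Lists that were not called reversed their direction, with the cause not tested, at these adjusted p: with no filter, NF-kB 0.632, hypoxia 0.854 and fibroblast markers 0.829; under quantile normalization, ferroptosis promoters 0.997, hypoxia 0.474 and ribosomal proteins 0.171; by fry, ferroptosis promoters 0.528, NF-kB 0.685, hypoxia 0.722 and ribosomal proteins 0.983; with the GC and length correction, ribosomal proteins 0.688. Over the fits that leave out 1 library, of which some reversed, adjusted p ran from 0.794 to 0.989 for ferroptosis promoters, 0.423 to 0.963 for the interferon response, 0.758 to 0.963 for NF-kB, 0.654 to 0.957 for TGF-beta, 0.808 to 0.95 for hypoxia and 0.0251 to 0.812 for ribosomal proteins, called without control CM replicate 2. Slc3a2, not called, reversed with that correction (log2 fold change 0.0012) and without control CM replicate 3 (-0.0386 to 0.0117 over the fits without 1 library).

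The values gave no sign of pairing by replicate number: same-numbered samples' deviations from their group means correlated at -0.023, -0.030 and 0.018 across genes. With so few samples this does not show whether they were paired when prepared. With the replicate block 622 genes were called (296 higher, 326 lower), 583 of them among the 801, and 10 lists.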

Other observations

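The tests of chance, of Col1a1, of the G2/M list, of the chromosome 2 cluster and of the AhR list were chosen after the results they measure were seen. The tests of GC content and length and of second gene lists were chosen after the patterns had been seen, but before their own values were looked at. The second lists were measured in the same libraries, so any other difference between the groups could move them too. A second list of NRF2 targets rose too: of 13 tested, 9 were higher and none lower by limma, with a median log2 fold change of 0.19. Camera called it higher (adjusted p = 1.75e-09, and adjusted p = 0.0264 with an estimated correlation). Its members included the heme transporter Slc48a1 (0.31), the esterase Esd (0.30), the epoxide hydrolase Ephx1 (0.30), the transporter Abcc4 (0.29) and isocitrate dehydrogenase Idh1 (0.28). A second list of ATF4 targets had a median of -0.10, with 5 of 16 lower and 1 higher (camera adjusted p = 0.00183, but adjusted p = 0.113 with an estimated correlation); the tRNA exporter Xpot (-0.25) and tyrosyl-tRNA synthetase Yars (-0.22) fell, and the amino acid transporter Slc1a4 (0.27) rose. A second list of S phase genes had a median of -0.12, with 6 of 25 lower and 1 higher (camera adjusted p = 2.69e-06, and adjusted p = 0.0264 with an estimated correlation), among them the primase subunit Prim1 (-0.25), with Rpa1 (0.14) higher.

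The rise of NRF2 targets was weighed against technical sources. Log2 fold changes followed GC content across genes (Spearman's rho -0.178; genes are not independent replicates), and control CM replicates 1 and 2 deviated from their group mean in opposite ways with GC (-0.142 and 0.152). With the trend removed the NRF2 list's median was 0.38, against 0.37 before, with 17 members higher, which argues against GC content and length as the whole cause. RNA of fibroblasts carried over with the medium would bring collagen; the difference in Col1a1 (Tdo2high CM minus control CM) was -0.03 FPKM, while the NRF2 list's median rise was 16.8 FPKM, which argues against that source for the list, although of the other fibroblast markers Npnt (0.46) and Pdgfra (0.17) rose and Dcn (-0.48) fell. A response shared by NRF2 targets stays open as a hypothesis. The second list (0.19) rose as well, but in the same libraries, so it is no independent repeat.

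The falls of ATF4 and S phase genes were also weighed. With the GC and length trend removed the medians were -0.15 and -0.14 (before, -0.18 and -0.14), with 12 and 7 members lower, so that trend does not account for the whole of either. If the S phase fall came from fewer cycling cells, G2/M genes would be lower too; their median was 0.0369, with 3 members higher and none lower, which argues against it. A change shared by each program may remain, as a hypothesis: the second lists moved the same way (-0.10 and -0.12), the ATF4 one losing its call with an estimated correlation.

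Zfp965 and Zfp973 went opposite ways within a chromosome 2 cluster of related genes (GRCm38, from 175016710 to 178078425). The median within-group SD of its 27 tested genes was 0.20 on the log2 scale, above all of 10000 expression-matched sets (percentile 100, matched median 0.08); in the treated group Zfp967 spanned 4.19 to 15.1 FPKM. Reads shared between paralogs could give this, but the spread had prompted the idea, and whether members' losses offset others' gains was undecided (percentile 19.5 of the matched sets), so this stays open. The cluster's summed FPKM was 158 ± 6.11 with control CM and 161 ± 5.46 with Tdo2high CM (SD, n = 3), a difference of 3.31 that argues against a change of the whole cluster.

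As a hypothesis, the AhR list's rise may come from enzymes that NRF2 also controls. Without Nqo1, Aldh3a1 and Ugt1a6a, the 5 other members had a median log2 fold change of 0.11. Camera gave p = 0.0366 at the preset correlation and p = 0.233 with an estimated correlation. Tiparp (0.25) and Cyp1b1 (0.16) were called higher by limma, while Ahr (0.11), Slc7a5 (-0.08) and Arnt (-0.04) were not called. The rises of Tiparp and Cyp1b1 thus lie outside the enzymes left out. Ahr is the receptor itself and Slc7a5 also stands on the ATF4 list. The set therefore tests AhR targets poorly, and whether NRF2-shared enzymes account for the list's rise is not decided. Of the 10 splits of the 6 libraries into 3 and 3, the real one was the 1 split that called 801 genes and the highest other called 1; 10 splits are too few for a share under 0.05.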
